A study of Mus musculus with 6 samples.

How the data were processed

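Expression was measured with Affymetrix MOE430A arrays in CD11c+ cells selected from the spleens of untreated mice, on 3 wild-type and 3 Atg16L1 hypomorph arrays. Per the labels' protocols, cells were selected with magnetic beads, RNA was extracted with TRIzol reagents, and labelled cDNA was prepared from total RNA. The labels differ in 2 details between samples: the title of wild-type replicate 3 names another version of the array, although its values cover the same probe sets, and the title of wild-type replicate 1 carries another run prefix than the others. Per the submitters' processing notes, values were made with Affymetrix Power Tools. The version, the background correction and the summarization method are not given in the sources used here. The deposited values are 1 log2 expression value per probe set and array. The log base was inferred from their range, from about 2 to 14.3, and is not stated, so fold changes depend on that inference. From the close medians and quartiles of the arrays it was inferred that the deposited log2 values had been normalized between arrays. Such normalization hides any difference in total RNA per cell. Arrays have no read depth, and their number limits the precision.

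The table held 22690 probe sets, of which 1 had no value on any array and 64 were Affymetrix controls. Genes were named from the platform annotation. Of the 22625 other probe sets, 20379 named exactly 1 gene, 691 named several and 1555 had none listed. The gene IDs of 20350 single-gene probe sets were found in a RefSeq gene table of the mouse genome, used only for names and gene order, and 0 symbols needed updating. Only single-gene probe sets were tested. Of the 12393 genes they cover, 4955 had several probe sets, and the one with the highest mean over all 6 arrays stood for the gene. Another probe set of the same gene passed the threshold in the opposite direction for 3 of the 56 named genes with other probe sets, H2-D1, Mcl1 and Pfkp. Of the 48 named genes past the threshold that have other probe sets, 15 had no other past it in the same direction: Ace, Atg5, Bak1, Ccr9, Cd40, Col1a2, Dnajb1, Hs6st2, Nfib, Pfkp, Ralgps2, Rpl22, Rpl27a, Rps15 and Vmp1.

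The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, robust fitting or a covariate, two-sided) on the deposited log2 values of all 6 arrays, with no filter on dim probe sets. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the plots. On data simulated from these 12393 genes and this comparison, limma recovered 34.3% of 67 genes changed by 0.5 on the log2 scale. It recovered 83.6% of 67 genes changed by 1 and 97% of 66 changed by 2. Both groups were simulated with the same spread. More genes were called in the data, and the spreads of the groups differed, so these shares do not give the sensitivity there. In that simulation 4 of 147 calls were unchanged genes, and 3.02% of 199 random gene lists had a camera p under 0.05. Genes were simulated independently of each other there, so that share does not show how camera behaves on lists of correlated genes.

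The tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The 34 lists hold 864 genes, of which 710 had a probe set of their own, and the other genes were not analysed here. A list gene absent under its current symbol was matched through synonyms only if the name is no longer a current symbol. That rule was tightened after a first run, in which 3 genes had been matched to others. The 33 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, and the sex-linked list was reported as values. Some lists share genes, with 3 of the 45 lysosomal and 1 of the 21 macrophage genes also in another list. The named genes are Atg16l1, the 10 largest changes each way among genes past the threshold whose groups did not overlap, 15 genes named in advance, 4 members of smallest p in the direction of each list past the threshold, and 1 member of every other list. Genes outside this rule are said to be named after their values were seen.

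Alternatives were the mean of a gene's probe sets, all probe sets one by one, filters at the median and lower quartile of level, quantile normalization, centring on array medians, eBayes with trend and robust fitting, array weights, the replicate number as a block, a minimum change of 1.5-fold, and leaving out each array in turn. For lists, camera with an estimated correlation and fry were added, and for the neighbours of Atg16l1 windows of 25 and 100 genes on either side. The mean poly-A spike-in signal as a covariate, and the fit without the 2 wild-type arrays of highest spike-in signal, which leaves 1 wild-type array, were chosen after seeing the data. Control classes were compared by exact permutation of array means. Intervals of list medians are 95% bootstrap intervals over genes from 10000 draws, which leave out the error between arrays. With the spike-in covariate, list means per array were also fitted on genotype and spike-in signal by least squares, with t intervals over arrays.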

Results

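Gene expression was measured in CD11c+ cells taken from mouse spleens with magnetic beads. CD11c is the integrin, encoded by Itgax, that is used to select dendritic cells, and some splenic macrophages also carry it. The mice were untreated, on the C57BL/6J background and 8 weeks of age, and the comparison was between 3 arrays from wild-type mice and 3 from mice hypomorphic for Atg16L1. A hypomorphic allele is one with reduced function, and Atg16L1 is part of the complex that attaches ATG8 proteins such as LC3 to the growing autophagosome membrane. The labels name replicates without saying that each came from its own animal, so p-values measure the spread between these samples. The precision of every value is limited by the 3 arrays per group.

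The deposited log2 values had close medians on all 6 arrays, from 5.65 to 5.71. Correlations across genes were 0.9861 to 0.9933 among wild-type arrays, 0.9939 to 0.9976 among hypomorph arrays and 0.9781 to 0.9872 between the groups, and the first principal component, with 58.6% of the variance, separated the genotypes. The spread between wild-type arrays was wider, with a median SD per gene of 0.142 against 0.089 in the hypomorph. Control probe sets also separated the genotypes. The 24 probe sets for poly-A spike-ins, bacterial transcripts added to the RNA before labelling, averaged 9.48 ± 0.50 (SD, n = 3) in wild type and 7.69 ± 0.18 in the hypomorph. The 18 hybridization controls averaged 11.35 ± 0.28 and 10.33 ± 0.06, and the 3 probe sets for 18S ribosomal RNA 9.43 ± 0.21 and 8.76 ± 0.06. The log2 difference between 3' and 5' probe sets of beta-actin was 0.973 ± 0.042 in wild type and 0.737 ± 0.039 in the hypomorph. In all 4 measures the 2 groups did not overlap, with a two-sided exact permutation p of 0.1 each, the smallest that 3 against 3 arrays can give. Every gene difference given here lies between groups that also differ in these controls.

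**Figure D1:**
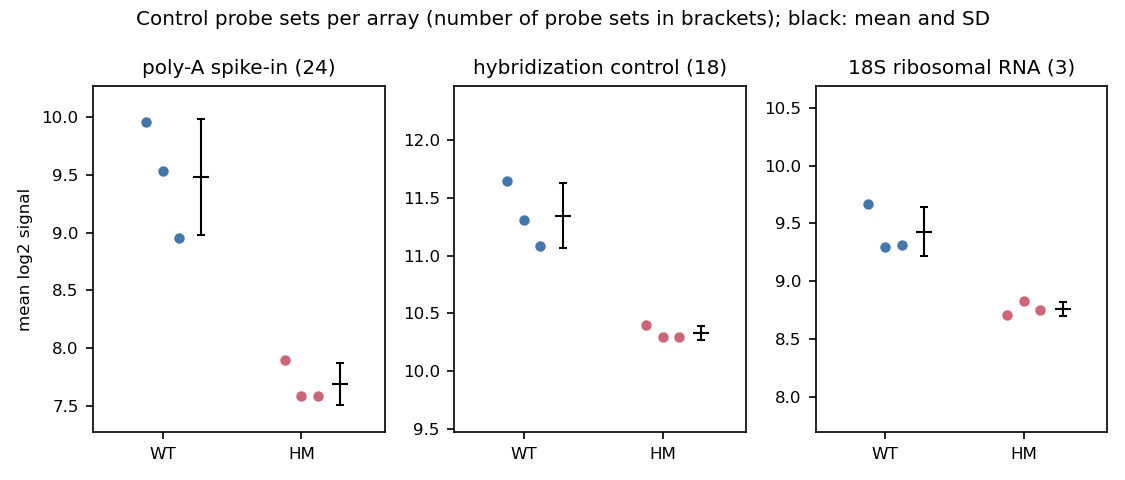
Mean log2 signal of 3 classes of control probe sets on each wild-type (WT, blue) and Atg16L1 hypomorph (HM, red) array, with the group mean and SD over 3 arrays in black. The hypomorph arrays lie below the wild-type arrays in each class, by 1.79, 1.02 and 0.67 on the log2 scale from left to right in the group means.

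Atg16l1 itself was lower in all 3 hypomorph arrays, at 6.03 ± 0.16 (SD, n = 3) against 7.07 ± 0.04 in wild type, a 2.05-fold decrease (log2 change -1.04, SE 0.097, adjusted p = 0.00163). It has a single probe set, and the labels do not say where the allele lies relative to it. The change was -0.91 (adjusted p = 0.493) with the spike-in level as a covariate, a setting chosen after seeing the data. Of 12393 genes tested with limma, 2260 differed between the genotypes at an adjusted p under 0.05, 1210 of them higher and 1050 lower in the hypomorph. Of these, 646 higher and 332 lower genes changed by at least 1.5-fold. The 3 arrays of each group did not overlap for 5080 genes, 41% of those tested, where chance gives 10%. Leaving out hypomorph replicate 1, 2 or 3 lowered the count of changed genes to 950, 834 and 742. With the spike-in level as a covariate no gene passed with limma (1149 at an unadjusted p under 0.05), so none of the member counts below held in that fit, in which the standard errors were 2.96 times as large (median over genes).

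Among the genes with the largest increases, several encode receptors and enzymes of macrophages. Ccr3, an eotaxin receptor, rose 6.09-fold, from 6.22 ± 0.49 to 8.83 ± 0.08. The Fc gamma receptor genes Fcgr4 and Fcgr1 rose 5.51-fold and 5.48-fold, the mannose receptor gene Mrc1 rose 5.04-fold, and Hmox1, which encodes the haem-degrading enzyme heme oxygenase 1, rose 5.46-fold from 8.85 ± 0.59 to 11.30 ± 0.26. Also among the 10 largest was the collagenase gene Mmp13 (log2 change 2.56, SE 0.26), which was dim in wild type at 3.51 ± 0.20. The others were the microRNA host locus annotated as Mir142 (2.54, SE 0.13), lipoprotein lipase Lpl (2.48, SE 0.34), the AP-1 gene Fosb (2.45, SE 0.38) and the glycosyltransferase gene B3galnt1 (2.39, SE 0.094). Their adjusted p-values lay between 0.000465 for B3galnt1 and 0.00826 for Fosb.

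Among the largest decreases were genes of the heat shock response. Dnajb1, a co-chaperone of HSP70, was 7.64-fold lower (11.64 ± 0.89 in wild type, 8.71 ± 0.30 in the hypomorph), the HSP70 gene Hspa1a 6.07-fold, Hsph1 5.89-fold, the small heat shock protein gene Hspb1 5.79-fold and the HSP70 co-chaperone gene Bag3 4.18-fold. The apelin receptor gene Aplnr was 4.65-fold lower, Hs6st2 4.33-fold, Igfbp7 3.74-fold, the transcription factor gene Nfib 3.71-fold and Gdpd2 3.62-fold. Adjusted p-values for these 10 ran from 0.00232 for Aplnr to 0.035 for Gdpd2. The calls of Hsph1, Hspb1, Bag3, Hs6st2, Nfib and Gdpd2 were lost when any 1 hypomorph array was left out, and that of Igfbp7 without hypomorph replicate 2 or 3. A second, dimmer probe set of Dnajb1 changed by -1.085 on the log2 scale with overlapping arrays and did not pass (adjusted p = 0.217), and the other probe sets of Hs6st2 and Nfib, all dimmer, did not pass either (adjusted p from 0.0689 to 0.469).

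Most genes of the list for red pulp and marginal zone macrophages rose together, and the list does not tell these cell types apart. Of 21 measured, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 change of 1.64. The strongest by p were Adgre1, which encodes F4/80 (4.32-fold, from 9.21 ± 0.36 to 11.33 ± 0.03), the complement gene C1qc (3.89-fold), Vsig4 (2.97-fold) and Cd5l (3.83-fold). The 3 members that did not pass were Siglec1 (log2 change 0.11), Gpnmb (-0.35) and Cd209b (-0.42), named after their values were seen. The list shifted against all other genes by camera with a preset correlation of 0.01 (adjusted p = 2e-14), and with an adjusted p = 0.24 with an estimated correlation. With any 1 array left out, 17 or 18 members rose. The poly-A spike-in signal was lower in the same arrays, by 1.79 on the log2 scale.

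Lysosomal genes rose as well. Of 45 measured, 33 rose and 0 fell (36 and 0 adjusted over the list alone), with a median log2 change of 0.49. They included the cathepsin genes Ctsb (2.36-fold, from 11.61 ± 0.15 to 12.85 ± 0.04) and Ctsl (2.53-fold), the acid phosphatase gene Acp2 (2.60-fold) and Cd68 (2.27-fold), which encodes a lysosomal membrane glycoprotein abundant in macrophages. Camera gave an adjusted p = 6.31e-20, and an adjusted p = 0.24 with an estimated correlation. The count was lowest, at 22, without hypomorph replicate 3. The macrophage list stood 1.64 higher in the same arrays and 41 of the 45 lysosomal genes were above the median gene already in wild type.

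**Figure D2:**
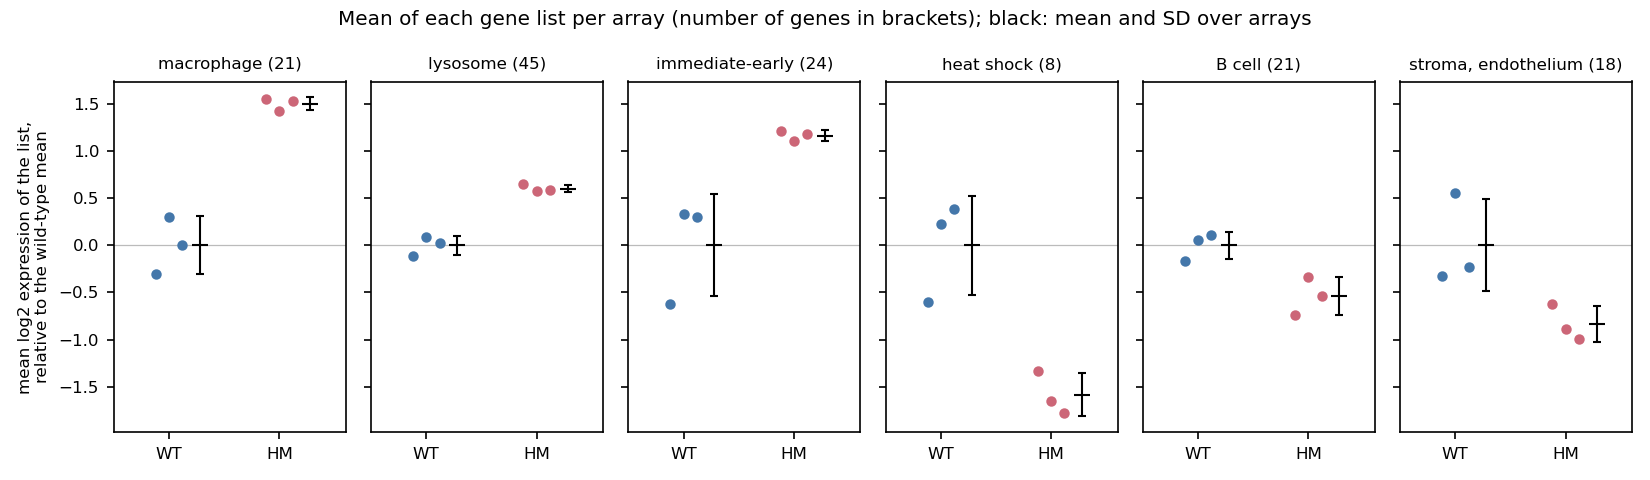
Mean log2 expression of 6 groups of genes on each wild-type (WT, blue) and Atg16L1 hypomorph (HM, red) array, relative to the wild-type mean, with the group mean and SD over 3 arrays in black and the number of genes in brackets. Macrophage, lysosome and immediate-early genes are higher in each hypomorph array than in any wild-type array, while heat shock, B cell and stromal genes are lower.

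Autophagy genes other than Atg16l1 moved in part. Of 32 genes for ATG8 conjugation and autophagosome formation, 7 rose and 2 fell (7 and 2 adjusted over the list alone). The ATG8 family genes Gabarapl1 and Map1lc3a rose 2.20-fold and 1.52-fold, the kinase gene Ulk2 2.13-fold, and Vmp1, which acts at autophagosome formation sites, 1.76-fold. The partner of ATG16L1 encoded by Atg5 rose 1.32-fold (7.23 ± 0.14 to 7.63 ± 0.04, adjusted p = 0.0283), a call that was lost without any 1 hypomorph array and not made by its 2 other probe sets (log2 change 0.393 and -0.06), while Atg7 (log2 change 0.41, adjusted p = 0.0794) and Map1lc3b (0.05, adjusted p = 0.69, and -0.05 after quantile normalization) did not pass. Besides Atg16l1 the gene that fell was Tecpr1 (1.51-fold), which encodes a tether of autophagosomes to lysosomes and is named after its value was seen. The list passed by camera (adjusted p = 0.0449, and adjusted p = 0.553 with an estimated correlation) with a median change of only 0.05. That call was lost after quantile normalization (adjusted p = 0.257) and without wild-type replicate 1 or 3 or hypomorph replicate 1, and 4 members rose when any hypomorph array was left out.

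Genes for selective autophagy receptors had 5 of 12 members higher and 1 lower (5 and 1 adjusted over the list alone), with a median of 0.23. Ncoa4, the receptor for ferritin, rose 2.32-fold (9.62 ± 0.13 to 10.83 ± 0.12), Wdfy3 1.72-fold, Sqstm1, which encodes the receptor and autophagy substrate p62, 1.61-fold and the ER-phagy receptor gene Tex264 1.55-fold. Camera gave an adjusted p = 0.00193 (adjusted p = 0.24 with an estimated correlation). With limma none of the receptor genes fell without wild-type replicate 3 or any 1 hypomorph array (1 at an unadjusted p under 0.05 in each case). Macrophage genes were higher (median 1.64) and poly-A spike-ins lower (-1.79) in the arrays in which these genes and the autophagy genes above were higher.

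**Figure D3:**
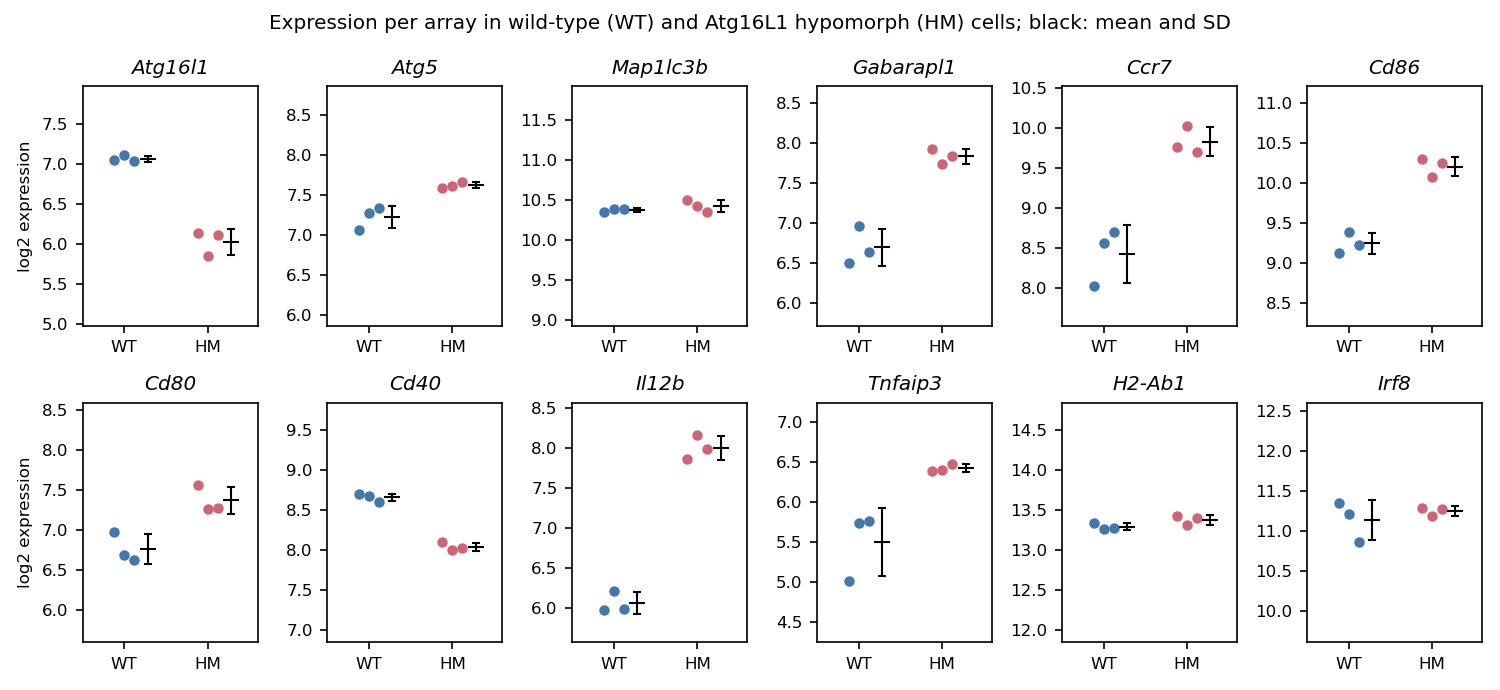
Log2 expression of 12 genes on each wild-type (WT, blue) and Atg16L1 hypomorph (HM, red) array, with the group mean and SD over 3 arrays in black; each panel spans 3 log2 units. By the probe sets shown, Atg16l1 and Cd40 are lower in each hypomorph array, Atg5, Gabarapl1, Ccr7, Cd86, Cd80, Il12b and Tnfaip3 are higher, and Map1lc3b, H2-Ab1 and Irf8 overlap.

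Genes of dendritic cell maturation went both ways. Of 28 measured, 8 rose and 5 fell (8 and 7 adjusted over the list alone). The homing receptor gene Ccr7 rose 2.65-fold (8.42 ± 0.36 to 9.83 ± 0.18) and the costimulatory ligand genes Cd86 and Cd80 1.95-fold and 1.53-fold, whereas Cd40 was 1.54-fold lower (8.66 ± 0.05 to 8.04 ± 0.05, adjusted p = 0.00306) by its brighter probe set and did not fall by the other (log2 change 0.035, adjusted p = 0.814). The list did not shift as a whole (camera adjusted p = 0.682), its median being -0.06 and its mean 0.08. Genes of the NF-kB pathway and its feedback also split, with 6 of 23 higher and 5 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.422). Itch, an E3 ubiquitin ligase gene, rose 1.46-fold, and Tnfaip3, which encodes the NF-kB inhibitor A20, rose 1.89-fold (adjusted p = 0.0231). Without hypomorph replicate 1, 2 or 3 the risen genes were 5, 3 and 3 for maturation and 1, 2 and 1 for NF-kB, and the fallen genes 4, 4 and 3 and 4, 1 and 1. Fewer fell without wild-type replicate 3 for maturation (3) and without any 1 wild-type array for NF-kB (3 each). Without any 1 hypomorph array the calls of Cd80 and Tnfaip3 were lost. The mean of the macrophage list was higher and the poly-A spike-in signal lower (-1.79) in the same arrays.

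Inflammatory cytokine and chemokine genes were higher as a group, with 11 of 30 risen and 0 fallen (12 and 0 adjusted over the list alone) and a median of 0.40. Il12b, the p40 subunit of interleukin 12 and interleukin 23, rose 3.84-fold (6.06 ± 0.14 to 8.01 ± 0.15, adjusted p = 0.000997). Il1a rose 2.41-fold, Il18 2.04-fold and Ccl2 1.88-fold. Il6 (log2 change 0.63, adjusted p = 0.229) and Tnf (0.16, adjusted p = 0.189) did not pass. Camera gave an adjusted p = 5.3e-06 (adjusted p = 0.24 with an estimated correlation), and without hypomorph replicate 1, 2 or 3 the risen members numbered 7, 6 and 6, while 1 fell without wild-type replicate 1. Of 20 Toll-like receptor and NOD signalling genes, 7 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.22. They included Tlr4 (3.60-fold), its co-receptor gene Ly96 (2.90-fold), the RNA sensor gene Tlr7 (2.58-fold) and Tlr2 (1.98-fold), with a camera adjusted p = 0.00156 (adjusted p = 0.24 with an estimated correlation), and 4 rose when any hypomorph array was left out. Type I interferon-stimulated genes had 4 of 32 members higher and 0 lower (4 and 0 adjusted over the list alone), namely Ifi204 (3.84-fold), Gbp2 (1.78-fold), Ifit3 (1.74-fold) and the RNA sensor gene Ifih1 (1.70-fold). Their camera adjusted p was 0.00329 (adjusted p = 0.681 with an estimated correlation), and the risen members numbered 8 without hypomorph replicate 1, 1 without replicate 2 or 3 and 2, with 1 fallen, without wild-type replicate 3. Relative to wild type their mean was -0.015 in hypomorph replicate 1, below wild-type replicate 1 (0.134), and 0.384 and 0.476 in hypomorph replicates 2 and 3 (exact permutation p = 0.2). Macrophages also express Tlr4, Ly96 and several of these cytokines, and their marker genes stood higher (median 1.64) in the same arrays, with poly-A spike-ins lower (-1.79).

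Genes of dendritic cell identity included higher and lower members. Among 13 pan-conventional dendritic cell genes, 2 rose and 3 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.413). Ccr7 and Cd83 (2.13-fold) rose. Itgax, which encodes CD11c, was 1.30-fold lower (10.32 ± 0.13 to 9.94 ± 0.07, adjusted p = 0.0341), the lineage factor gene Zbtb46 1.54-fold lower and the MHC class II transactivator gene Ciita 1.90-fold lower. Cd83, Itgax, Zbtb46 and Ciita are named after their values were seen, and when 1 hypomorph array was left out 1 member rose and 1 or 2 fell. Of 17 genes of the cDC1 subset, which cross-presents antigen, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0834), led by the adhesion gene Cadm1 (2.67-fold), and the lineage factor gene Irf8 did not differ beyond the spread (11.14 ± 0.25 and 11.25 ± 0.06, adjusted p = 0.594). Of 20 cDC2 genes 5 rose and 3 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.393), led by the lectin gene Clec4a2 (2.64-fold), with 1 fallen without hypomorph replicate 2 or 3, and Irf4 was 0.54 higher on the log2 scale without passing (adjusted p = 0.053). Of 18 plasmacytoid dendritic cell genes 5 rose and 1 fell (6 and 3 adjusted over the list alone), including Tlr7, Ccr9 (1.83-fold), Lag3 (1.67-fold) and Atp1b1 (1.43-fold), with a camera adjusted p = 0.0321 (adjusted p = 0.553 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.141) and without wild-type replicate 2 or 3 or hypomorph replicate 2, and 3 members rose without hypomorph replicate 1 and 2 without wild-type replicate 3 or hypomorph replicate 2 or 3; with limma none fell without hypomorph replicate 3 (1 at an unadjusted p under 0.05).

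The class II gene H2-Ab1 was at 13.30 ± 0.04 in wild type and 13.38 ± 0.06 in the hypomorph (adjusted p = 0.464). Of 14 MHC class II presentation genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.262), with the lysosomal protease gene Lgmn highest at 3.47-fold. Of 15 MHC class I presentation genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.0771), and with limma none rose when any 1 hypomorph array was left out. H2-D1 rose 1.28-fold by the probe set with the highest mean, and another of its 8 other probe sets fell past the threshold. Macrophage genes were higher (median 1.64) and poly-A spike-ins lower (-1.79) in the arrays in which these identity and presentation genes moved.

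Immediate-early and heat shock genes, fixed as 1 list of 32, held 18 members that rose and 7 that fell (21 and 7 adjusted over the list alone). Split after the values were seen, 18 of 24 immediate-early genes rose and 0 fell, with a median of 1.28, while 7 of 8 heat shock genes fell and 0 rose, with a median of -1.43. Among the immediate-early genes, Klf4 rose 3.26-fold, Fos 2.78-fold (11.98 ± 0.39 to 13.45 ± 0.05), Ier5 2.0-fold and Jund 1.75-fold. Camera called the whole list higher (adjusted p = 0.000103, and adjusted p = 0.672 with an estimated correlation). Wild-type replicate 1 was 0.62 below the wild-type mean for the immediate-early genes and 0.60 below it for the heat shock genes. With any hypomorph array left out 11 members of the list rose, and 4, 3 and 3 fell without replicate 1, 2 and 3 and 4 without wild-type replicate 3. The 2 groups of genes moved in arrays whose poly-A spike-in signal was lower by 1.79 and whose 3' to 5' difference in beta-actin was smaller.

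Markers of B cells and of stroma, cell types outside the intended CD11c+ selection, were lower in the hypomorph. Of 21 B cell genes 12 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.62. They included Ralgps2 (2.19-fold), Bach2 (2.0-fold), the antigen receptor component gene Cd79a (1.73-fold) and Cd22 (1.67-fold, from 10.21 ± 0.06 to 9.47 ± 0.16), with a camera adjusted p = 8.9e-05 (adjusted p = 0.553 with an estimated correlation). Without hypomorph replicate 1 or 3 the fallen genes numbered 6 and 4, and with limma none rose without any 1 array (1 at an unadjusted p under 0.05 in each case). Of 18 stromal and endothelial genes 9 fell and 0 rose (11 and 1 adjusted over the list alone), with a median of -0.87. Igfbp7, the matrix genes Sparc (3.19-fold) and Bgn (2.96-fold) and the collagen gene Col1a2 (2.82-fold) were lower, with a camera adjusted p = 0.00193 (adjusted p = 0.656 with an estimated correlation). With limma none of the stromal genes fell without hypomorph replicate 2 or 3 (11 at an unadjusted p under 0.05 in each case), and 4 fell without replicate 1, while 1 rose without wild-type replicate 2. Relative to the wild-type mean, stromal genes stood at 0.559 in wild-type replicate 2 and at -0.325 and -0.233 in replicates 1 and 3, and their median change was -0.544 without replicate 2. Poly-A spike-ins were lower (-1.79) and macrophage genes higher (median 1.64) in the same arrays.

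Monocyte genes had 6 of 19 members higher and 1 lower (8 and 2 adjusted over the list alone), with a median of 0.22. Ms4a6d rose 4.57-fold, the CSF1 receptor gene Csf1r 2.17-fold, Mpeg1 1.82-fold and Ace 1.49-fold, with a camera adjusted p = 0.0077 (adjusted p = 0.24 with an estimated correlation, and 0.065 after quantile normalization), and 2 fell without wild-type replicate 3 and none with limma without hypomorph replicate 3 (2 at an unadjusted p under 0.05). The median was 0.344 without hypomorph replicate 1. Macrophages also express Csf1r, Mpeg1 and Ms4a6d, and their marker genes stood higher (median 1.64) in the same arrays. Erythroid genes had a median of 0.77, but 1 of 19 rose (1 adjusted over the list alone), the biliverdin reductase gene Blvrb (2.53-fold). Blvrb did not follow the mean of the list. In hypomorph replicate 3 it stood at 10.13, against 8.85 ± 0.07 in wild type, while the erythroid mean there was -0.16 relative to wild type. The next by p, Epb42, Tspo2 and Rhag, had log2 changes of 0.98, 0.28 and 1.17 with overlapping arrays. The erythroid mean was 0.61, -0.55 and -0.06 in wild-type replicates 1, 2 and 3 and 1.04, 0.99 and -0.16 in hypomorph replicates 1, 2 and 3. Its camera call (adjusted p = 0.015, and adjusted p = 0.683 with an estimated correlation) was lost without wild-type replicate 2 or 3 or hypomorph replicate 1 or 2, and 2 genes rose without hypomorph replicate 3 and 1 fell without wild-type replicate 2. The erythroid median was 0.247 without wild-type replicate 2 and 0.386 without hypomorph replicate 1. Lists for 5 other cell types did not pass by camera. None of 20 T cell genes passed with limma (2 lower at an unadjusted p under 0.05; 0 adjusted over the list alone), the closest being Cd2 (log2 change -0.62, adjusted p = 0.0517; camera adjusted p = 0.254), and 3 fell without wild-type replicate 1. None of 16 NK cell genes passed (4 lower unadjusted; 0 over the list alone), with Serpinb9b at -0.69 (adjusted p = 0.0769; camera adjusted p = 0.901), and 1 fell without wild-type replicate 1 and 3 without wild-type replicate 2. Of 20 granulocyte genes 2 rose and 2 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.282), with Cxcr2 1.78-fold lower; 1 rose and 1 fell without any 1 hypomorph array, and 4 rose without wild-type replicate 2. Of 11 megakaryocyte and platelet genes 1 rose, the lectin receptor gene Clec1b (2.92-fold), and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.262), and 1 fell without wild-type replicate 1 or 2 or any 1 hypomorph array. Of 12 plasma cell genes 1 fell, the immunoglobulin joining chain gene Jchain (3.31-fold; 2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.636), while 2 rose without wild-type replicate 1 or 3 and 4 fell without wild-type replicate 2.

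**Figure D4:**
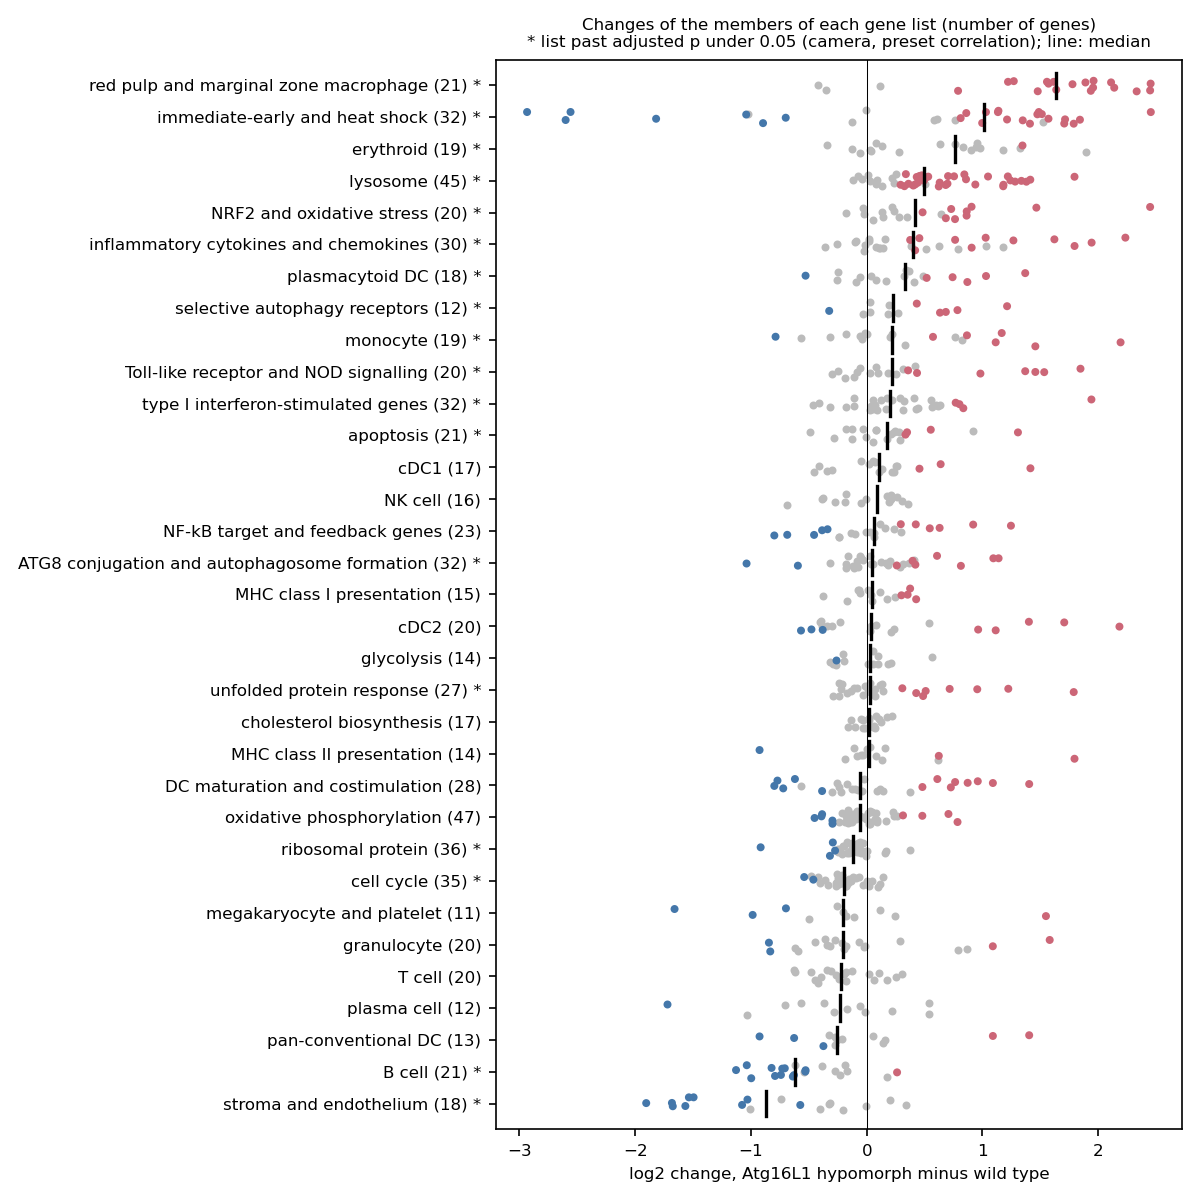
Log2 change (Atg16L1 hypomorph minus wild type) of each member of 33 gene lists, with the number of measured genes in brackets; red and blue points passed an adjusted p under 0.05 as higher and lower, grey points did not, and the black line is the list's median. Asterisks mark lists past an adjusted p under 0.05 by camera with the preset correlation, none of which passed with an estimated correlation.

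Of 20 NRF2 and oxidative stress genes 9 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.42. Besides Hmox1 they included Gsta4 (2.76-fold), the glutathione synthesis gene Gclm (1.87-fold) and the ferritin heavy chain gene Fth1 (1.82-fold), with a camera adjusted p = 2.14e-06 (adjusted p = 0.24 with an estimated correlation). Of 27 unfolded protein response genes 8 rose and 0 fell (8 and 1 adjusted over the list alone), among them Dnajb9 (1.94-fold), Sdf2l1 (1.64-fold), Herpud1 (1.42-fold) and the chaperone gene Hspa5 (1.40-fold). Its camera call (adjusted p = 0.0468, and adjusted p = 0.553 with an estimated correlation) was lost after quantile normalization (adjusted p = 0.319) and without wild-type replicate 2 or 3 or hypomorph replicate 1 or 3, and 4, 4 and 3 members rose without hypomorph replicates 1, 2 and 3 and 1 fell without wild-type replicate 2. Of 21 apoptosis genes 4 rose and 0 fell (6 and 1 adjusted over the list alone), namely Pmaip1 (2.47-fold), Ripk3 (1.47-fold), Mcl1 (1.27-fold, with another of its 5 other probe sets past the threshold in the opposite direction) and Bak1 (1.26-fold), with a camera adjusted p = 0.017 (adjusted p = 0.24 with an estimated correlation), and 2 rose without any 1 hypomorph array and 2 fell without wild-type replicate 1. Macrophage genes were higher (median 1.64) and poly-A spike-ins lower (-1.79) in the same arrays.

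Ribosomal protein genes were slightly lower, with a median of -0.12 against -0.05 for all genes. Of 36, 4 fell and 0 rose (2 and 0 adjusted over the list alone), namely Rpl27a (1.89-fold), Rps15 (1.25-fold), Rps19 (1.22-fold) and Rpl22 (1.21-fold), with a camera adjusted p = 0.00957 (adjusted p = 0.24 with an estimated correlation, and 0.0705 without wild-type replicate 2). Without hypomorph replicates 1, 2 and 3 the fallen genes numbered 1, 1 and 0 with limma (6, 8 and 7 at an unadjusted p under 0.05), without wild-type replicate 2 or 3 they numbered 2, and 1 rose without wild-type replicate 1. Of 35 cell cycle genes 2 fell, Mcm7 (1.45-fold) and Ccne1 (1.38-fold), and 0 rose (1 lower adjusted over the list alone), while Mcm5 and Tyms had log2 changes of -0.36 and -0.22 without passing. Its camera call (adjusted p = 0.0451, and adjusted p = 0.76 with an estimated correlation) was lost without wild-type replicate 1 or 3 or hypomorph replicate 3, and 16 members fell without wild-type replicate 2, 1 without wild-type replicate 3 and with limma none without hypomorph replicate 1, 2 or 3 (3, 2 and 2 at an unadjusted p under 0.05). The genotypes overlapped in the mean of these genes (exact permutation p = 0.4), which relative to wild type was -0.346 in wild-type replicate 2, below the hypomorph arrays (-0.127, -0.164 and -0.278), and 0.214 and 0.132 in wild-type replicates 1 and 3. Of 47 oxidative phosphorylation genes 4 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.835), with Cox7c 1.72-fold higher, and with limma none fell without hypomorph replicate 1, 2 or 3 (6, 6 and 5 at an unadjusted p under 0.05) and 3 without any 1 wild-type array. Of 14 glycolysis genes 1 fell, Pfkp (1.20-fold; 0 adjusted over the list alone; camera adjusted p = 0.932), and its other probe set passed in the opposite direction; with limma none fell without wild-type replicate 2 or 3 or any 1 hypomorph array (2 to 5 at an unadjusted p under 0.05). None of 17 cholesterol biosynthesis genes passed with limma (0 at an unadjusted p under 0.05, 0 over the list alone; camera adjusted p = 0.544), and Mvk was closest at a log2 change of 0.22 (adjusted p = 0.241). In the same hypomorph arrays macrophage genes were higher (median 1.64), and B cell genes (median -0.62) and the 18S ribosomal RNA controls (-0.665) lower. Xist was at 12.94 ± 0.11 in wild type and 12.64 ± 0.09 in the hypomorph, lower on each hypomorph array than on any wild-type array (adjusted p = 0.0602 over all genes and 0.0498 over the 4 sex-linked genes alone), and the Y-linked genes measured were near the lowest values on every array.

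The genes nearest to Atg16l1 in the gene order did not stand out as a group. Of the 100 nearest measured genes, 50 on either side, 12 differed between the genotypes (12%, against 18.2% of all genes tested). These went both ways and included Itm2c, which was higher (log2 change 0.65, limma adjusted p = 0.0086). Sag, a dim gene at 3.98 in wild type, was lower (-0.63, adjusted p = 0.0107). Both are named after their values were seen. The mean absolute moderated t of the 100 genes was 1.79 against 2.19 over all genes, at percentile 5.11 of 10385 windows of as many consecutive genes. The percentile was 1.45 with 25 genes on either side and 27.13 with 100. Genes are not independent replicates, so the percentile is a description of these arrays.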

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

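The spike-in covariate was chosen after the data had been seen, its test on the macrophage genes before that test's result, and the other tests in this part after their results, and the rule for reading it on the heat shock and immediate-early genes was changed after earlier versions had been run.

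Control probe sets, outside the main measurement, differed between the genotypes. Hypomorph minus wild type, the mean log2 difference was -1.792 for poly-A spike-ins, -1.017 for hybridization controls and -0.665 for 18S ribosomal RNA, each with no overlap between the arrays of the 2 groups and an exact two-sided permutation p of 0.1, the smallest possible. The spike-in level correlated at -0.945 with genotype across the 6 arrays, so a fit with both terms separates them poorly.

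Macrophage and lysosomal genes were higher in the hypomorph arrays. A candidate explanation is a larger share of red pulp macrophages among the bead-selected cells, since beads against CD11c do not exclude macrophages that carry it. It predicts a larger change in macrophage markers than in lysosomal genes, and the medians differed by 1.14 (95% interval over genes 0.86 to 1.49). Both medians were known when that prediction was written, and the interval leaves out the error between arrays. The difference is therefore no test of cell share, which stays open. Abundant markers such as Cd5l and Mrc1 stood at 11.91 and 11.51 in the hypomorph. Of the 21 markers, 17 were above the median gene in wild type too, and Hmox1 is also in the NRF2 list. A difference in the amount of sample RNA against spike-ins stays open: with the spike-in covariate the macrophage median was 0.97 (median SE 0.49, against 1.64 and 0.18 without it), 0 members passed as standard errors had grown, and over arrays the mean changes of the macrophage genes (1.1, 95% interval -0.78 to 3.03) and of the lysosomal genes (0.45, -0.21 to 1.1) had intervals that include 0, although the lysosomal median was 0.50 against 0.49 and camera, which treats genes as nearly independent, passed both lists (adjusted p = 1.58e-08 and 2.97e-10). A change of lysosomal genes within dendritic cells cannot be told apart from a change in cell share here, since over the 6 arrays the mean of the lysosomal genes followed that of the macrophage genes (0.997) and both separate the genotypes.

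Heat shock genes were lower and immediate-early genes higher in the hypomorph arrays. A handling response that moves both groups the same way cannot alone give their medians of -1.43 (95% interval over genes -2.6 to -0.7) and 1.28 (0.95 to 1.51). The list was split after these signs were seen, so this restates the pattern and is no separate test. Among wild-type replicates 1, 2 and 3 both groups moved together. Relative to the wild-type mean, heat shock genes stood at -0.602, 0.221 and 0.381 and immediate-early genes at -0.624, 0.327 and 0.297. For the heat shock genes, a difference in the amount of sample RNA against spike-ins finds no support in the medians, which went from -1.43 (median SE 0.25) to -2.27 (0.72) with the spike-in covariate and which camera, treating genes as nearly independent, called lower at an unadjusted p under 0.05, but it stays open because 0 passed as standard errors had grown and the change of their mean over arrays was -2.83 with a 95% interval of -5.69 to 0.04. For the immediate-early genes it stays open too, with a median of 0.03 (median SE 0.57) with the covariate against 1.28 (0.23), 0 past the threshold, and a mean over arrays of -0.15 with an interval of -2.6 to 2.29. Genotype and separate handling of the samples of each genotype also stay open, as untested.

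Stromal and B cell genes were lower in the hypomorph arrays. A lower share of dendritic cells in the wild-type selection might raise markers of every other cell type there. The stromal median was -0.87 (95% interval over genes -1.5 to -0.32) beside a macrophage median of 1.64 (1.48 to 1.96), so macrophages were not part of such a rise. These signs were known when that prediction was written, so the difference is no separate test. Over arrays the mean of the megakaryocyte and platelet genes also fell (-0.24, 95% interval -0.41 to -0.08). The intervals of T cell, NK cell, granulocyte, plasma cell and erythroid genes included 0, which leaves the explanation open. Some macrophages carry CD11c and can be selected with dendritic cells, so their genes cannot speak on carry-over of cells without CD11c. Of 13 pan-conventional dendritic cell genes 2 rose and 3 fell in the hypomorph, which does not settle their share. The stromal median was -0.544 without wild-type replicate 2, the 1 wild-type array with a raised stromal mean, and the interval of the stromal mean over arrays (-1.67 to 0.01) includes 0. Over arrays the mean of the macrophage genes rose by 1.5 (95% interval 1 to 2) in the hypomorph, which bears on macrophages only. The mean of the B cell genes fell by 0.54 (interval -0.93 to -0.14). With the spike-in covariate the B cell mean changed by -1.15 (-2.24 to -0.07) and the stromal mean by -0.63 (-4.02 to 2.75). The intervals of plasmacytoid dendritic cell, Toll-like receptor and ribosomal protein genes also left out 0 in that fit. Such intervals are not adjusted for the number of lists. A difference in stromal and B cell carry-over alone, with abundant genes such as Ighm (13.94 in wild type, 12.90 in the hypomorph, named after its values were seen) and Igfbp7 (11.49 and 9.58), was not tested apart from genotype and stays open.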

How the results depend on the processing

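The fits with the spike-in covariate and without the 2 wild-type arrays of highest spike-in signal were chosen after seeing the data; the latter leaves 1 wild-type array (replicate 3), so its spread comes from the hypomorph arrays alone and its calls say nothing about stability. The 2260 changed genes became 1231 with the replicate block, 978 with a minimum of 1.5-fold, 0 with the spike-in covariate and 1473 without those 2 arrays, and lay between 742 and 2272 with 1 array left out (950, 834 and 742 without hypomorph replicate 1, 2 and 3); the other 8 alternatives gave 2245 to 2801. The labels do not say what the replicate numbers mark. Deviations of same-numbered samples correlated at 0.153, 0.011 and 0.106, and those of differently numbered samples at -0.173 to 0.138. Atg16l1 changed by -0.91 with the spike-in covariate (adjusted p = 0.493) and by -1.09 to -0.946 with 1 array left out. The 18 lists past camera became 11 with the median filter, 0 with an estimated correlation (smallest adjusted p = 0.24) and 13 to 17 with 1 array left out; other settings gave 13 to 21. The percentile of the neighbours of Atg16l1, 5.11, became 1.45 with 25 and 27.13 with 100 genes on either side, and 4.58 to 8.89 with 1 array left out. The fewer genes under the fold minimum follow from its construction, and the larger standard errors under the covariate from its correlation with genotype; otherwise the cause was not tested.

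Of 115 named genes besides Atg16l1, 100 passed, of which all 100 lost their call with the spike-in covariate, 16 with the block, and 20, 27 and 30 without hypomorph replicate 1, 2 and 3. These log2 changes turned sign: with the mean of probe sets Pfkp (0.077) and Mcl1 (-0.031); after quantile normalization Map1lc3b (-0.054) and Irf8 (-0.017); with 1 array left out Irf8 (-0.028 to 0.212, the negative value without wild-type replicate 3); with the spike-in covariate Tnfaip3 (-0.244), Il6 (-1.28), Atg5 (-0.044), Atg7 (-0.029), Irf4 (-0.361), Gbp2 (-0.01), Ccne1 (0.091), Rpl27a (0.103) and Mcl1 (-0.067). None of these passed.

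Camera's direction turned for these lists, given by their median log2 change. For glycolysis it was 0.056 with the mean of probe sets, 0.031 with the block and -0.016 to 0.032 with 1 array left out. For NF-kB it was 0.032 with the median filter and 0.048 with the covariate. For NK cells it was -0.097 with the median filter, 0.108 after quantile normalization, -0.066 with array weights, 0.085 with fry, -1.077 with the covariate, -0.277 without the 2 wild-type arrays and -0.108 to 0.288 with 1 array left out. For cholesterol biosynthesis it was 0.017 with the median filter, -0.216 with the covariate, -0.053 without the 2 wild-type arrays and -0.034 to 0.083 with 1 array left out. For plasma cells it was -0.322 to 0.019 with 1 array left out and 0.104 with the covariate. For oxidative phosphorylation it was -0.07 to -0.042 with 1 array left out (-0.056 where the direction turned) and 0.065 with the covariate. With the covariate it was also -0.067 for maturation, 0.074 for pan-conventional dendritic cells, -0.005 for megakaryocytes and -0.287 for immediate-early and heat shock. Of these, NK cells and immediate-early and heat shock passed with the covariate; NK cells were also past the threshold against wild-type replicate 3 alone, the array with the highest NK mean (0.328 above the wild-type mean), which is no evidence of a change. Why the directions of these lists turned was not tested. Leaving that fit aside, lists that passed only under alternatives were T cells (in 3 settings, -1.206 with the covariate, adjusted p = 1.23e-08), cDC1 (in 5), MHC class I (in 2), oxidative phosphorylation (after quantile normalization) and, with fry alone, MHC class II, cDC2, granulocytes and megakaryocytes.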

Other observations

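The gene families in this part were chosen after the data had been seen; the tests of the neighbours of Atg16l1 and of other splits of the arrays were planned.

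Genes grouped by the stem of their symbol were tested by camera, and 2 of 226 families of at least 8 genes passed, neither with an estimated correlation (adjusted p = 0.828 for both). Of 56 genes with the stem Rab, most of them small GTPases of vesicle traffic, 13 rose and 0 fell, with a median log2 change of 0.13 (adjusted p = 0.00911). They included Rab20 (3.71-fold), Rab31 (1.76-fold), Rab38 (1.69-fold) and Rab32 (1.46-fold), and also Rab3il1 (2.52-fold), which encodes a Rab3-interacting protein and no GTPase. Of 13 immunoglobulin kappa variable genes (stem Igkv), 4 fell and 0 rose, with a median of -0.67 (adjusted p = 0.00915). The brightest, Igkv8-30, was 2.64-fold lower (12.83 ± 0.41 in wild type, 11.43 ± 0.13 in the hypomorph), and Igkv6-14 was 3.02-fold lower. In the same arrays macrophage and lysosomal genes were higher (medians 1.64 and 0.49), and B cell genes (median -0.62) and the poly-A spike-in signal (-1.792) lower.

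An allele made in another strain can carry flanking DNA that changes expression of the genes around it. Spread over many genes, such an effect would put the mean absolute moderated t of the 100 genes nearest to Atg16l1 above percentile 95 of windows of that size. That mean was at percentile 5.1 (1.79 against 2.19 over all genes), which argues only against a spread effect larger than the differences found elsewhere. A smaller spread effect could not be seen against those differences. A mean over 100 genes cannot exclude an effect on a few of them, since 18.2% of all genes tested also differed between the genotypes.

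Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed genes as the genotypes (2260), namely the real one, and the highest of the others was 0 with limma (145 to 413 genes at an unadjusted p under 0.05 in the other splits, 4210 in the real one). The splits are too few for a share under 0.05.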
